A study of Mus musculus with 4 samples.

How the data were processed

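Total RNA of 2 samples of NSCL61 and 2 samples of NSCL61-sox11 was purified on silica columns, labelled with biotin by in vitro transcription and hybridised to Affymetrix M430_2 arrays, with 1 array per sample, per the labels' protocols and descriptions. The deposited table holds the authors' processed value of each of 45101 probe sets on each array. The deposited values were read as log2 because they run from 2.13 to 14.62 with none missing; their log base is inferred from this range and not stated. How the authors summarised and normalized the probes is not given in the sources used here. The arrays were already on a common scale, with means of 6.21 to 6.22 after trimming 2% of values, so the deposited values were used without further scaling. The 3' minus 5' difference of the control probe sets was -0.01 to 0.04 for Gapdh and 0.28 to 0.34 for actin (log2).

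Probe sets were named through GEO's platform annotation, with symbols checked through gene identifiers against the gene table of the mouse assembly GRCm38.p6, which updated 0 symbols. Of the non-control probe sets, 932 have several symbols and 9160 none here, and 34945 have 1 symbol. Neither of the former groups was given a gene name, and 64 control probe sets were left out of the tests. The same gene table gave each gene's chromosome and neighbours; no positions are printed because the values name no genome build. A gene was represented by its tested probe set with the highest mean level, and 6085 genes had more than 1 tested probe set.

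The lines were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided) on the 60% of probe sets with the highest mean, 27022 in all with means of at least 5.15. P-values were adjusted by the Benjamini-Hochberg method over these probe sets and called under 0.05. A second threshold was a log2 fold change of at least 1, which is 2-fold. The design leaves 2 residual degrees of freedom, and 6.36 after moderation. Probe sets below the level filter were tested only in a fit of all probe sets, which the text names where it is used. Errors beside levels are SD over the 2 arrays of a line; errors beside log2 fold changes are moderated SE. Figures were drawn with matplotlib 3.10.9.

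Before the data were examined, 26 gene lists were written down. They cover neuronal differentiation, proneural and neuronal transcription factors, synapse and ion channels, neural stem and progenitor cells, the oligodendrocyte lineage, astrocytes, S phase and DNA replication, G2 and mitosis, and cell cycle inhibitors and exit. Others cover Ras and MAPK output, the imprinted gene network, Notch, Hedgehog, Wnt, and BMP and TGF-beta signalling, extracellular matrix and invasion, axon guidance and migration, interferon response, and stress responses. The rest cover hypoxia and glycolysis, cholesterol synthesis, apoptosis, growth factor receptors and glioma oncogenes, and markers of microglia and blood cells, of endothelial and mural cells, and of fibroblasts and meninges. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 26 lists. The same test with an estimated correlation was an alternative. The rotation test fry was another, and it asks whether the genes of a list move in 1 direction, not how they compare with other genes.

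The genes to be named were also set by a rule beforehand. They are Sox11, Plagl1 and the deleted gene of these cells, the 10 largest rises and 10 largest falls among called genes whose arrays do not overlap between the lines (unnamed clones left out), and up to 4 called members of each list with the largest change, or the 2 brightest members where none was called. Not all of them are described. The deleted gene is not reported here. Hox genes other than Hoxd8 and Hoxd9, the chromosome comparison and genes that differ between arrays of a line were chosen after the values were seen.

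The scripts were tested on simulated data. Noise for 27022 simulated probe sets was drawn from limma's fitted variance prior. Among them, 19.4% of 67 changed 1.5-fold, 82.1% of 67 changed 2-fold and 100% of 66 changed 4-fold were recovered, with 10 false calls. A first version of this simulation drew its noise from shrunken variances and exceeded its bound on false calls, so it was redrawn from this prior. The redrawn noise follows limma's own model, so the false calls do not test that model. Far fewer probe sets were changed than the 4678 called in the data, so the recovered shares cannot be read as shares recovered in the data. Among 26 simulated lists the 1 list lowered by 0.5 was recovered and 1 other was called. In a simulation of 13058 genes in which 1 chromosome was lowered by 0.2, that chromosome was called and 0 of 19 others were. Genes were drawn independently or shuffled in these simulations. They therefore do not measure false calls of lists or chromosomes whose genes vary together.

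Alternatives fixed beforehand were quantile normalization, median centring, no level filter or a filter at the brightest 40%, no intensity trend, the replicate number as a block, leaving out each array in turn, other rules for representing a gene, the other list tests and, in place of a test, a 2-fold difference with no overlap of arrays. Scaling to the poly-A spike-ins or hybridisation controls, taking off each chromosome's median, and leaving Plagl1 out of the lists were chosen after seeing the data. With 2 arrays per line, no test for outlying arrays and no regrouping of arrays was run.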

Results

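Gene expression was measured on Affymetrix mouse arrays in NSCL61, a line of p53-deficient neural stem cells from embryonic mouse telencephalon that the labels describe as resembling glioma-initiating cells, and in NSCL61-sox11, a derivative that expresses the transcription factor Sox11. There were 2 arrays per line, 4 in all, each with 45101 probe sets. The submitters' design text states that the derivative no longer formed tumours after transplantation, and the comparison asks which genes differ between the lines. Nothing states that the arrays of a line came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical, and NSCL61-sox11 is represented by 1 line. The number of arrays limits the precision: the smallest two-sided p of an exact permutation test of 2 arrays against 2 is 0.333, and the calls below rest on limma, which shares variance information across probe sets.

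Arrays of the same line were closer to each other than arrays of different lines. Across the 27022 probe sets tested, which are not independent replicates, Pearson's r was 0.995 within NSCL61 and 0.994 within NSCL61-sox11, and 0.968 to 0.972 between the lines. The SD of the difference between 2 arrays was 0.19 and 0.22 log2 units within the lines and 0.47 to 0.50 between them.

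The genes with the largest changes included the transcription factor gene Plagl1, which rose in NSCL61-sox11, and the neurofilament light chain gene Nefl, which fell. In total 2510 of 13084 genes changed between the lines at an adjusted p under 0.05, 1308 upwards and 1202 downwards. Among probe sets, 4678 of 27022 changed, 2429 upwards and 2249 downwards. Rises were more frequent among large changes: 416 genes rose and 170 fell at least 2-fold, and 739 probe sets rose and 308 fell at least 2-fold. For 11 genes, among them Actb and Pcbp2, different probe sets were called in opposite directions. Leaving out NSCL61 array 1 lowered the count to 908 genes (533 up, 375 down) and 1639 probe sets (941 up, 698 down), and leaving out NSCL61 array 2 lowered it to 944 genes (637 up, 307 down) and 1701 probe sets (1133 up, 568 down). The balance of directions thus depended on the arrays used, and also on the filter and scaling. With the brightest 40% of probe sets 1161 genes rose and 1222 fell, and with median centring 1173 rose and 1376 fell. With arrays scaled to the poly-A spike-in controls, every log2 fold change was 0.404 lower, the median of all genes was -0.42, and 303 genes rose and 1051 fell (558 and 1995 probe sets, and 470 and 974 probe sets at least 2-fold). With arrays scaled to the hybridisation controls, the median was -0.24, and 702 genes rose and 2336 fell (1242 and 4656 probe sets, and 573 and 546 probe sets at least 2-fold). The size of a change is uncertain where 1 line lies below 5.15, the lowest mean of a tested probe set. Among genes named below this holds for NSCL61-sox11 in Nefl, Hoxd8, St8sia4, Eomes and Naalad2, and for NSCL61 in Sox11, Plagl1, Mme, Defb41, Scg2, Ebf1, Gbp2 and Perp. Directions below are relative to the scale of the deposited values, on which the median of all genes was -0.02.

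Sox11, an HMG-box transcription factor, was higher in NSCL61-sox11 on each of its 6 probe sets. On its representative probe set, the level was 4.95 ± 0.19 (SD, n = 2) in NSCL61 and 7.85 ± 0.16 (SD, n = 2) in NSCL61-sox11. This is a 7.45-fold rise, with a log2 fold change of 2.90 (SE 0.14, limma adjusted p = 0.00013). Among its other probe sets the smallest rise was 0.38 (adjusted p = 0.047). Plagl1, a zinc finger transcription factor and imprinted gene, rose from 4.89 ± 0.33 to 9.51 ± 0.48 (SD, n = 2 each) on its only tested probe set, a log2 fold change of 4.62 (SE 0.25, limma adjusted p = 0.00019). The name of this probe set ends in _x_at, so the alternative that leaves such probe sets out gave no value for Plagl1. The other Plagl1 probe sets lay below the level filter. In the fit of all probe sets 1 of them rose by 1.09 (adjusted p = 0.031), and the other differed by 0.04 (adjusted p = 0.88).

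Among the other large rises, Sorbs2, which encodes an adaptor protein of the actin cytoskeleton, rose 16.8-fold on its brightest probe set. Of its 3 tested probe sets 2 were called, and their mean gave a log2 fold change of 1.53. Vgll3, a cofactor of TEAD transcription factors, rose 14.8-fold, from 5.19 ± 0.24 to 9.08 ± 0.26 (SD, n = 2 each). Eya4, a transcriptional coactivator and phosphatase, rose 14.3-fold, and the membrane peptidase gene Mme rose 13.3-fold. For Mme this was 8.02-fold without NSCL61 array 1, 20.6-fold without NSCL61-sox11 array 1 and 8.55-fold without NSCL61-sox11 array 2, and its log2 fold change of 3.73 became 4.46 without NSCL61 array 2. Gnai1, a G protein subunit, rose 11.7-fold, the defensin gene Defb41 10.6-fold, and Lhx2, a LIM homeobox factor of the developing forebrain, 10.4-fold. Igfbp2, which binds insulin-like growth factors, rose 10.2-fold. Postn, which encodes the matrix protein periostin, rose 10.1-fold, but its NSCL61-sox11 arrays lay at 8.27 and 10.59. Its log2 fold change of 3.33 became 4.49 without NSCL61-sox11 array 1 and 2.17 without NSCL61-sox11 array 2. Its call was lost without NSCL61 array 1 (adjusted p = 0.12) or NSCL61 array 2 (adjusted p = 0.068).

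Nefl fell from 11.40 ± 0.55 in NSCL61 to 4.62 ± 0.42 (SD, n = 2 each) in NSCL61-sox11, a log2 fold change of -6.78 (SE 0.29, limma adjusted p = 0.00010). The homeobox genes Hoxd8 and Hoxd9 fell by 5.44 and 2.81 on the log2 scale. St8sia4, a polysialyltransferase, fell 24.3-fold, or 8.02-fold with the mean of its probe sets. Bex1 fell 13.5-fold from a level of 13.61, and Eomes, a T-box factor of cortical intermediate progenitors, fell 10.1-fold. The glucose transporter gene Slc2a3 fell 9.32-fold, Ociad2 8.88-fold, the peptidase gene Naalad2 8.31-fold and Syt14, a synaptotagmin, 6.85-fold.

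**Figure D1:**
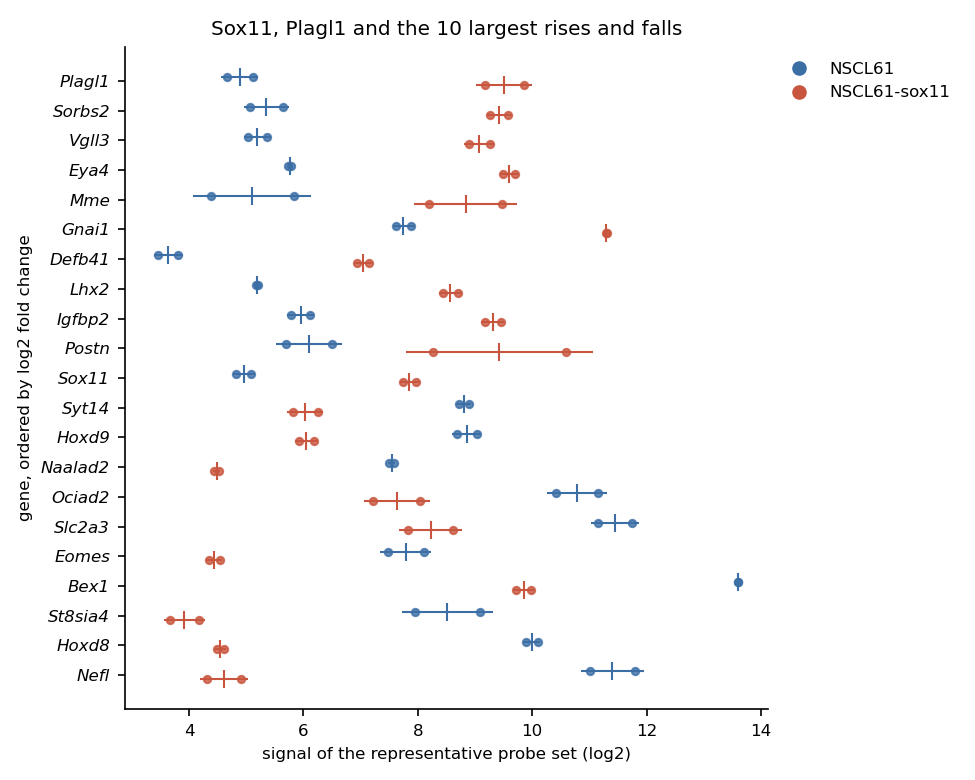
Levels (log2, x axis) of Sox11, Plagl1 and the genes with the 10 largest rises and 10 largest falls (y axis, ordered by log2 fold change). Points are arrays, vertical ticks are group means and horizontal bars are SD (n = 2). The arrays of the lines do not overlap for any of these genes, which the rule for choosing the largest rises and falls required. Log2 fold changes run from 4.62 for Plagl1 to -6.78 for Nefl.

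Gene lists were fixed before the data were examined, and 9 of 26 shifted against the other genes with camera at its preset correlation, 7 upwards and 2 downwards. With an estimated correlation, where the test has 2 degrees of freedom, 0 were called and 1 had an unadjusted p under 0.05. A scaling to control probe sets moves every log2 fold change by the same amount and can turn the sign of a small median.

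The imprinted gene list and the list of cell cycle inhibition and exit were higher in NSCL61-sox11 as groups, relative to other genes. The latter is not made of inhibitors alone, as it also holds the D-type cyclin genes Ccnd1, Ccnd2 and Ccnd3. Of 23 imprinted genes tested, 10 rose, 1 fell and 12 did not pass (11 and 1 adjusted over the list alone), with a median of 0.36 that became -0.04 with poly-A scaling (camera adjusted p = 0.0033, and adjusted p = 0.55 with an estimated correlation). The median was 0.12 without NSCL61 array 1, 0.06 without a level filter, 0.58 with the brightest 40% of probe sets and 0.21 without Plagl1. Beside Plagl1, Asb4 rose 6.79-fold, Dlk1, which encodes a membrane ligand of the Notch family, rose 5.91-fold from 9.12 to 11.69, and the amino acid transporter gene Slc38a4 rose 4.64-fold. Of 31 genes of cell cycle inhibition and exit, 10 rose, 1 fell and 20 did not pass (12 and 2 adjusted over the list alone), with a median of 0.23 that became -0.18 with poly-A scaling (camera adjusted p = 0.0042, and adjusted p = 0.60 with an estimated correlation). Klf9, a Krüppel-like factor, rose 4.58-fold, Gas1, a growth arrest gene and Hedgehog co-receptor, 3.96-fold, and Ndrg1 2.93-fold. The call of this list was lost without NSCL61-sox11 array 2 (adjusted p = 0.090). Plagl1 belongs to both lists, and both calls held without it. The definitions of these lists also share Cdkn1c and Ndn, which were not left out, so the calls are not independent. Other lists share members too, as Gas1 is also in the Hedgehog list.

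Markers of fibroblasts and meninges had the largest median among the lists. Of 14 tested, 8 rose, none fell and 6 did not pass (11 and 1 adjusted over the list alone), with a median of 0.81 (camera adjusted p = 0.00012, and adjusted p = 0.58 with an estimated correlation). Without a level filter the median was 0.41. The risers included Igfbp2, Postn, the collagen gene Col1a1 (7.93-fold, from 6.08 ± 0.33 to 9.06 ± 0.78, SD, n = 2 each) and Pdgfrb, a receptor of platelet-derived growth factor (5.04-fold). Of 55 genes of extracellular matrix, invasion and mesenchyme, 17 rose, 10 fell and 28 did not pass (18 and 11 adjusted over the list alone), with a median of 0.09 that became -0.31 with poly-A scaling (camera adjusted p = 0.19). The median was 0.03 without NSCL61 array 1, -0.02 without NSCL61-sox11 array 2 and -0.06 with the mean of all probe sets of a gene. The cross-linking enzyme gene Lox rose 5.64-fold and the protease inhibitor gene Timp3 5.12-fold. Without NSCL61 array 2 or without NSCL61-sox11 array 1 the median of this list was 0.12. The list was called with poly-A scaling (camera adjusted p = 0.00027) or hybridisation control scaling (camera adjusted p = 0.00042). These scalings move all log2 fold changes by the same amount and leave the list's place among those of other genes unchanged. Camera compares changes relative to their errors, which these scalings alter, so its p-value moved. The calls under these scalings therefore add no support for a rise. Of 36 growth factor receptors and glioma oncogenes, 9 rose, 6 fell and 21 did not pass (11 and 9 adjusted over the list alone; camera adjusted p = 0.30). Pdgfra rose 3.76-fold and Fgfr2 2.60-fold, and Sox2, a stem cell transcription factor, fell 3.24-fold from a level of 10.52.

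Of the signalling lists, the BMP and TGF-beta and the Hedgehog genes were higher in NSCL61-sox11 relative to other genes. Among 37 BMP and TGF-beta genes, 14 rose, 1 fell and 22 did not pass (14 and 4 adjusted over the list alone), with a median of 0.23 that became -0.18 with poly-A scaling (camera adjusted p = 0.00042, and adjusted p = 0.58 with an estimated correlation). The median was 0.14 without NSCL61 array 1 and 0.15 without NSCL61-sox11 array 2. The ligand genes Bmp4 and Tgfb2 rose 5.95-fold and 4.40-fold, and Id4 and Ccn2, which respond to these pathways, rose 4.54-fold and 4.48-fold. Among 15 Hedgehog genes, 5 rose, none fell and 10 did not pass (6 and 0 adjusted over the list alone), with a median of 0.27 that became -0.13 with poly-A scaling (camera adjusted p = 0.0011, and adjusted p = 0.55 with an estimated correlation). The transcription factor gene Gli2 rose 4.94-fold and the co-receptor gene Cdon 3.59-fold. The receptor gene Ptch1 rose 1.46-fold and lost its call without NSCL61 array 1 (adjusted p = 0.18), NSCL61 array 2 (adjusted p = 0.083) or NSCL61-sox11 array 2 (adjusted p = 0.052). Among 31 Wnt genes, 7 rose, 4 fell and 20 did not pass (7 and 5 adjusted over the list alone; camera adjusted p = 0.36), with the receptor genes Fzd2 and Fzd8 up 2.30-fold and 2.27-fold and Wnt7b down 2.66-fold. Among 26 Notch genes, 3 rose, 1 fell and 22 did not pass (3 and 1 adjusted over the list alone; camera adjusted p = 0.31). These were Dlk1, Dtx4 (2.52-fold), Dtx3 and, downwards, Psen2; Dtx3 lost its call without NSCL61 array 1 (adjusted p = 0.076) or array 2 (adjusted p = 0.12), and Psen2 without NSCL61 array 2 (adjusted p = 0.081). Among 37 genes of Ras and MAPK output, 3 rose, 8 fell and 26 did not pass (5 and 10 adjusted over the list alone), with a median of -0.19 (camera adjusted p = 0.16). The phosphatase gene Dusp4 fell 2.71-fold from 11.07 ± 0.07 to 9.63 ± 0.31 (SD, n = 2 each) and Epha4 rose 7.94-fold. The median shrank to -0.12 without NSCL61 array 1 or NSCL61-sox11 array 1, and the list was called, downwards, without NSCL61-sox11 array 2 (adjusted p = 0.0060).

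**Figure D2:**
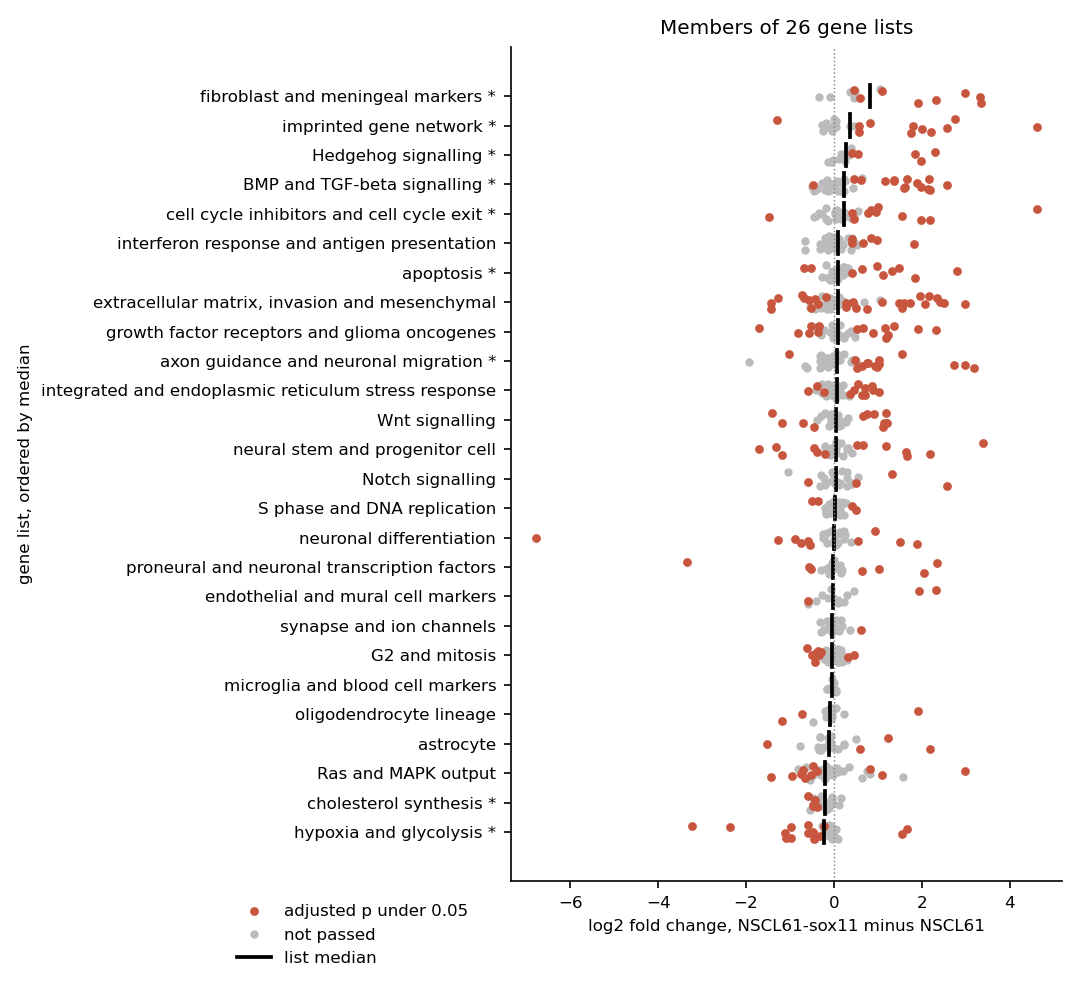
Log2 fold changes (x axis, NSCL61-sox11 minus NSCL61) of the tested members of 26 gene lists (y axis, ordered by median). Red points passed an adjusted p of 0.05, grey points did not, black bars are list medians, and an asterisk marks the 9 lists called by camera at the preset correlation. The medians run from -0.22 for hypoxia and glycolysis to 0.81 for fibroblast and meningeal markers. With poly-A scaling every point would lie 0.404 lower.

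Neuronal genes moved in both directions. Among 41 genes of axon guidance and neuronal migration, 13 rose, 1 fell and 27 did not pass (16 and 4 adjusted over the list alone), with a median of 0.08 that became -0.33 with poly-A scaling (camera adjusted p = 0.040, and adjusted p = 0.60 with an estimated correlation). The chemokine gene Cxcl12 rose 9.11-fold, from 9.14 ± 0.02 to 12.33 ± 0.15 (SD, n = 2 each), the guidance cue genes Ntn1 and Slit2 rose 6.68-fold and 2.92-fold, and Epha4 is also a member. The call was lost without NSCL61-sox11 array 2 (adjusted p = 0.11) and with quantile normalization (adjusted p = 0.061) or with chromosome medians taken off (adjusted p = 0.081). Among 27 neuronal differentiation genes, 4 rose, 6 fell and 17 did not pass (5 and 6 adjusted over the list alone; camera adjusted p = 0.74). Tubb3, a neuronal tubulin, rose 2.82-fold and the secretogranin gene Scg2 3.74-fold, while Uchl1 fell 2.40-fold beside Nefl. Among 20 proneural and neuronal transcription factors, 4 rose, 3 fell and 13 did not pass (4 and 4 adjusted over the list alone; camera adjusted p = 0.70), with Ebf3 and Ebf1 up 5.06-fold and 4.17-fold and Eomes down. Of 20 synapse and ion channel genes, 1 rose and 19 did not pass (1 and 0 adjusted over the list alone; camera adjusted p = 0.96). This was the vesicle protein gene Syt1 at 1.53-fold, and it lost its call without NSCL61 array 1 (adjusted p = 0.054) or array 2 (adjusted p = 0.074).

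Stem cell and glial lists also split. Of 30 neural stem and progenitor genes, 7 rose, 6 fell and 17 did not pass (10 and 6 adjusted over the list alone; camera adjusted p = 0.36). Lhx2, Id4 and Id2 rose, the last 3.15-fold, and Sox2 fell; Id2 lost its call without NSCL61 array 1 (adjusted p = 0.067) or array 2 (adjusted p = 0.057). Of 18 oligodendrocyte lineage genes, 1 rose, 2 fell and 15 did not pass (1 and 2 adjusted over the list alone; camera adjusted p = 0.31), with Pdgfra up and the proteoglycan gene Vcan down 2.27-fold. Of 21 astrocyte genes, 3 rose, 1 fell and 17 did not pass (3 and 1 adjusted over the list alone; camera adjusted p = 0.74). Slc4a4, a bicarbonate transporter gene, rose 2.35-fold, and the metallothionein gene Mt3 fell 2.87-fold, a call lost without NSCL61 array 2 (adjusted p = 0.076).

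Genes of proliferation changed little as groups. Of 38 genes of S phase and DNA replication, 2 rose, 2 fell and 34 did not pass (1 and 2 adjusted over the list alone), with a median of 0.03 that became -0.38 with poly-A scaling (camera adjusted p = 0.86). The median was 0.07 without NSCL61 array 1, -0.02 without NSCL61 array 2, -0.11 without NSCL61-sox11 array 1 and 0.13 without NSCL61-sox11 array 2. The replication factor gene Rfc3 and the histone mRNA-binding protein gene Slbp rose by 0.51 and 0.42 on the log2 scale, and the ribonucleotide reductase genes Rrm2 and Rrm1 fell by 0.49 and 0.36. Of 43 genes of G2 and mitosis, 2 rose, 9 fell and 32 did not pass (2 and 10 adjusted over the list alone), with a median of -0.04 (camera adjusted p = 0.30) that was -0.09 without NSCL61-sox11 array 1, -0.07 without NSCL61 array 2, -0.01 without NSCL61 array 1 and -0.00 without NSCL61-sox11 array 2. Pimreg fell by 0.61 and Dlgap5 by 0.50, and the kinesin gene Kif11 rose by 0.47. Without NSCL61 array 1 the calls of Rfc3 (adjusted p = 0.15), Slbp (0.11), Rrm2 (0.079), Rrm1 (0.11), Pimreg (0.054), Dlgap5 (0.10) and Kif11 (0.12) were lost. Without NSCL61 array 2 those of Rfc3 (0.23), Slbp (0.14), Rrm1 (0.13), Dlgap5 (0.085) and Kif11 (0.11) were lost. Without NSCL61-sox11 array 1 the rise of Rfc3 was 0.32 and its call was lost (0.076).

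Metabolic lists were lower in NSCL61-sox11, but for cholesterol synthesis this depended on the arrays used. Of 31 genes of hypoxia and glycolysis, 13 fell, 2 rose and 16 did not pass (13 and 2 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 0.00012, and adjusted p = 0.55 with an estimated correlation). Beside Slc2a3, the adenylate kinase gene Ak4 fell 5.15-fold, from 8.49 ± 0.23 to 6.13 ± 0.15 (SD, n = 2 each). Ndrg1 and the prolyl hydroxylase gene P4ha2 rose 2.93-fold and 3.17-fold. Of 23 genes of cholesterol synthesis, 5 fell, none rose and 18 did not pass (5 and 0 adjusted over the list alone), with a median of -0.21 (camera adjusted p = 0.010, and adjusted p = 0.76 with an estimated correlation). The estimated correlation between the genes of this list was 0.93, far above the preset 0.01. At the preset value, camera counts genes that moved together as nearly independent. The list's median also differed by 0.34 between the NSCL61-sox11 arrays, more than between the lines. Tm7sf2 fell by 0.59, Msmo1 by 0.48, Fdft1 by 0.47 and Idi1 by 0.42 on the log2 scale. The list's call was lost without NSCL61 array 2 (adjusted p = 0.072) or NSCL61-sox11 array 1 (adjusted p = 0.41). Its median was -0.05 without NSCL61-sox11 array 1, -0.46 without NSCL61-sox11 array 2 and -0.32 without NSCL61 array 1. Without NSCL61 array 1 the adjusted p of these 4 genes was 0.072 to 0.18, and without array 2 it was 0.16 to 0.23. Without NSCL61-sox11 array 1 it was 0.082 for Tm7sf2 and 0.059 for Fdft1, and the falls of Fdft1 and Msmo1 shrank to 0.31 each. Only 1 of 4 tested probe sets of Fdft1 was called.

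Apoptosis genes were higher as a group, relative to other genes. Of 35 tested, 8 rose, 2 fell and 25 did not pass (10 and 2 adjusted over the list alone), with a median of 0.10 that became -0.31 with poly-A scaling (camera adjusted p = 0.014, and adjusted p = 0.60 with an estimated correlation). The median was 0.15 without NSCL61-sox11 array 2. The members that rose included both promoters and inhibitors of cell death: Perp rose by 2.81 on the log2 scale, Pmaip1, which encodes the pro-apoptotic protein Noxa, 3.60-fold, the inflammatory caspase gene Casp1 2.78-fold and Birc3, an inhibitor of apoptosis, 2.50-fold. The call was lost with the brightest 40% of probe sets (adjusted p = 0.13). Of 38 genes of the integrated and endoplasmic reticulum stress response, 9 rose, 3 fell and 26 did not pass (9 and 3 adjusted over the list alone; camera adjusted p = 0.17), among them Cebpb, a transcription factor gene, at 1.85-fold. Of 36 genes of interferon response and antigen presentation, 6 rose, none fell and 30 did not pass (7 and 0 adjusted over the list alone), with a median of 0.10 that became -0.30 with poly-A scaling (camera adjusted p = 0.19). The guanylate-binding protein gene Gbp2 rose 3.52-fold. The median was 0.27 without NSCL61-sox11 array 1, where the list was called upwards (adjusted p = 0.0052), and -0.03 without NSCL61-sox11 array 2 (adjusted p = 0.88).

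Markers of other cell types were tested as well. None of 9 markers of microglia and blood cells passed limma's threshold (0 and 0 adjusted over the list alone, 0 at an unadjusted p under 0.05; camera adjusted p = 0.71; adjusted p = 0.40 with fry, which tests for a change in 1 direction and not against other genes), and Cd14 was at 8.44 in NSCL61 and 8.48 in NSCL61-sox11. Of 15 endothelial and mural markers, 2 rose, 1 fell and 12 did not pass (3 and 3 adjusted over the list alone; camera adjusted p = 0.74). Those that rose were Pdgfrb and Rgs5, a pericyte gene, at 3.85-fold.

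Some calls of smaller changes named above depended on other settings. Cebpb, Fzd2, Fzd8, Slc4a4 and Rrm1 lost their calls with poly-A scaling, and Ptch1, Dtx3, Syt1 and Kif11 with both control scalings (adjusted p from 0.052 for Fzd2 to 0.86 for Kif11 with poly-A scaling). Dlgap5 lost its call with chromosome medians taken off (adjusted p = 0.061) and Psen2 with the mean of all probe sets of a gene (adjusted p = 0.055), as did Ptch1 (adjusted p = 0.061). Fdft1 lost its call with both, at -0.26 (adjusted p = 0.20) and -0.24 (adjusted p = 0.12). Rfc3 and Slbp lost theirs with both control scalings and with the mean of all probe sets (adjusted p = 0.052 and 0.11), and Rfc3 also with median centring, without a level filter, without the intensity trend and with chromosome medians taken off (adjusted p = 0.050 to 0.067). With the mean of all probe sets the change was 9.23-fold for Eya4, 8.76-fold for Mme, 5.42-fold for Eomes, 5.64-fold for Cxcl12, 3.62-fold for Ntn1 and 5.03-fold for Col1a1, and Hoxd8 fell by 4.43. In the same setting the log2 fold changes of Ak4, Cdon, Ebf1, Rgs5 and Slc4a4 shrank from -2.36, 1.84, 2.06, 1.94 and 1.23 to -1.49, 1.11, 1.35, 1.23 and 0.68. Fdft1 and Msmo1 lost theirs with quantile normalization (adjusted p = 0.053 and 0.057), and these 2 and Idi1 without the intensity trend (adjusted p = 0.062 to 0.072). For 4 uncalled lists the median, mean and test direction differed in sign. The proneural transcription factors had a median of -0.01 and a mean of 0.07 (test upwards), and the endothelial and mural markers a median of -0.02 and a mean of 0.22 (upwards). The astrocyte genes had a median of -0.12 and a mean of 0.02 (downwards), and the synapse genes a median of -0.03 and a mean of -0.00 (upwards). Without NSCL61-sox11 array 2 the median of the proneural factors was 0.05 and that of the endothelial and mural markers 0.10, and without NSCL61-sox11 array 1 that of the synapse genes was 0.03.

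Changes were also unevenly spread over the chromosomes, a comparison chosen after the values were seen. Of 13058 genes placed on 20 chromosomes, those of chromosome 14 had a median log2 fold change of -0.21 (418 genes, 78.0% lower) and those of chromosome 12 a median of -0.16 (458 genes, 75.5% lower). The median was -0.10 on chromosome 7 (1031 genes) and 0.11 on chromosome 10 (624 genes, 67.9% higher). Each of these 4 lay farther from the others' level than all 10000 random gene lists matched on level (permutation p = 0.0001, the smallest these draws can give, adjusted p = 0.00033). The direction held in each of the 4 pairings of an NSCL61-sox11 with an NSCL61 array, with medians of -0.23 to -0.20 on chromosome 14 and 0.08 to 0.16 on chromosome 10. With poly-A scaling all of these medians would lie 0.404 lower, so that of chromosome 10 would be below 0. Smaller medians past the same test, 0.00 to 0.05, were found on chromosomes 4, 5, 13, 17 and 19. Chromosome 17, with a median of 0.004, passed narrowly (permutation adjusted p = 0.044, from a p rounded to 0.02). The random lists draw single genes, so the test makes no allowance for neighbouring genes that vary together. It also does not measure variation between arrays or lines. A small chromosome median can hide regional shifts. Medians of blocks of about 50 neighbouring genes ran from -0.18 to 0.18 on chromosome 4 and from -0.11 to 0.22 on chromosome 5. They ran from -0.17 to 0.16 on chromosome 1, which did not pass the test.

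**Figure D3:**
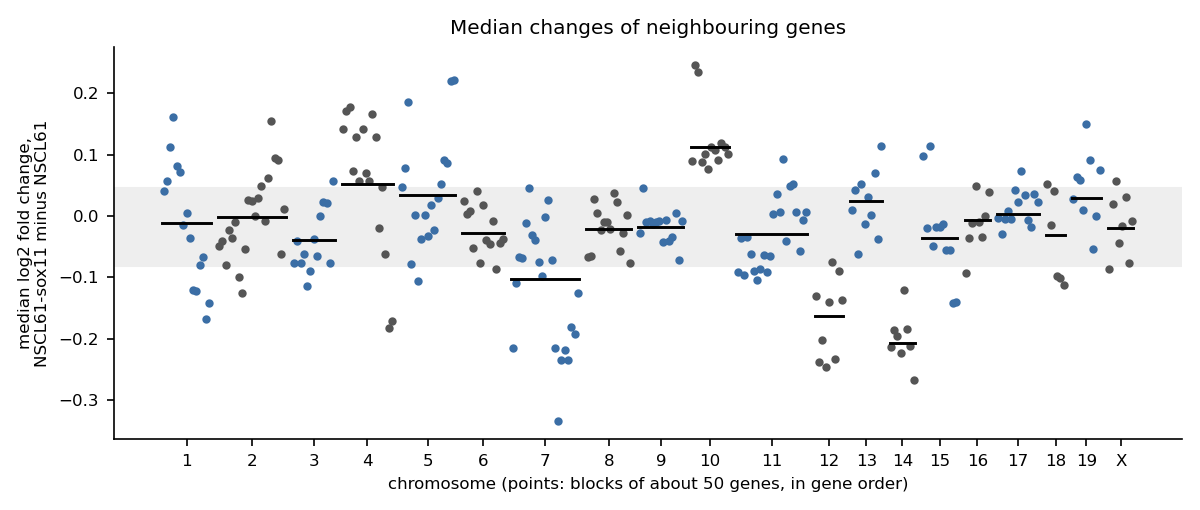
Median log2 fold change (y axis, NSCL61-sox11 minus NSCL61) of blocks of about 50 neighbouring genes (points, in gene order along each chromosome, x axis). Black lines are chromosome medians, and the grey band holds the middle 90% of blocks of 50 genes drawn at random. All 8 blocks of chromosome 14 lie below the band and all 12 blocks of chromosome 10 above it, on the scale of the deposited values; with poly-A scaling every point would lie 0.404 lower, with those of chromosome 10 below 0.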

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

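The tests in this part were chosen after the result was seen. The control probe sets, which no comparison between the lines uses, held a signal that differed between the lines. The 24 probe sets of the poly-A spike-ins, transcripts usually added to the RNA before labelling, averaged 7.33 and 7.03 on the NSCL61 arrays and 7.74 and 7.42 on the NSCL61-sox11 arrays, a difference of 0.404. All 24 were higher in NSCL61-sox11, by 0.20 to 0.67. Several of these probe sets read the same spike-in transcript, so they are not 24 separate observations. The hybridisation controls, added after labelling, were at 9.98 and 9.99 in NSCL61 and 10.10 and 10.31 in NSCL61-sox11, a difference of 0.217.

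A candidate explanation is brighter hybridisation of the NSCL61-sox11 arrays. The poly-A minus hybridisation control level differed between the lines by 0.187 and between the arrays of NSCL61-sox11 by 0.539. That spread exceeds even the whole poly-A difference of 0.404, so this test had little chance to fail and leaves the explanation open. Less mRNA per total RNA in NSCL61-sox11 stays open too: the lower NSCL61-sox11 array lay -0.238 from the higher NSCL61 array in this level. Such an overlap had been set down as evidence against it, but the spread between arrays of a line is larger than the difference between the lines and decides nothing.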

How the results depend on the processing

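The scalings to spike-ins and hybridisation controls, the chromosome correction and the lists without Plagl1 were chosen after seeing the data. Of the 2510 genes called, 2403 were shared with quantile normalization, 2375 with median centring, 2257 without a level filter and 2064 without the intensity trend, and no gene was called in the opposite direction under any alternative. Sox11 kept its call under each alternative that could give a value, with a log2 fold change of 1.65 to 3.06. The filter at the brightest 40% removed it and gave none. Pseudocount alternatives were not run because the values are already logarithms.

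Counts moved by more than 1.5 times in these cases. Leaving out an array gave 1639 to 4947 probe sets and 908 to 2692 genes, against 4678 and 2510. The lower counts came without NSCL61 array 1 or 2, and the cause was not tested. In each of these fits the lone array is assumed to vary like the other line. The array left out ended the calls of 24 and 22 of 98 named genes for NSCL61 arrays 1 and 2, and of 5 and 3 for NSCL61-sox11 arrays 1 and 2. Poly-A scaling gave 2553 probe sets and 1354 genes, of which 1174 were shared. The poly-A level differed between the arrays of NSCL61 (7.33 and 7.03) and of NSCL61-sox11 (7.74 and 7.42). Scaling to it therefore adds spread within each line to every probe set, and its share in the lost calls was not tested. A rule of at least 2-fold with no overlap of arrays and no test gave 1082 probe sets. With an estimated correlation 0 of 26 lists were called, against 9, with 2 degrees of freedom, and 1 had an unadjusted p under 0.05. The rotation test fry asks another question, whether a list moves in 1 direction, and called 10. Cholesterol synthesis (adjusted p = 0.43) and cell cycle inhibitors (0.11) were not among them; neural stem and progenitor cells (0.032), proneural factors (0.039) and Notch (0.039) were.

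With the replicate number as a block (replicate block), 9227 probe sets and 4830 genes were called, all 2510 among them, and the extracellular matrix list was called (adjusted p = 0.047). The labels do not say that equal numbers share a culture, and there are only 2 pairs. Deviations of same-numbered arrays correlated at 0.41 across probe sets, which is a hint from the data and not from the design. The number of arrays and the dim signal of the probe sets left out by the filter limit what can be called.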

Other observations

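Of the tests in this part, those of level, of neighbouring genes and of array-to-array variation were chosen after the result was seen; those of copy number and of fibroblast-like cells were written down before. Beside Hoxd8 and Hoxd9 their neighbour Hoxd10 fell. In the fit of all probe sets, the 4 of 10 Hoxd probe sets called belong to these 3 genes, the others differed by -0.41 to 0.08, and Hoxd10 fell from 6.93 to 2.71 (n = 2 each), a level too low to size the change. Of 16 Hoxa probe sets 3 rose and none fell, of 11 Hoxb probe sets 1 rose and none fell, and of 11 Hoxc probe sets 0 were called by limma, with 1 at an unadjusted p under 0.05. Those that rose were 1 probe set each of Hoxa10, Hoxa9 and Hoxb6, from dim NSCL61 levels of 2.94, 4.74 and 4.14 that leave the size of the change uncertain, and 1 of Hoxa5, by 0.90. The brighter probe sets of Hoxa9 and Hoxa5 differed by 0.09 (adjusted p = 0.59) and -0.23 (adjusted p = 0.15), and another of Hoxa10 by -0.18. These genes, which pattern the body axis, were chosen after their values were seen.

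Some genes differed between arrays of the same line in the same direction in both lines. Fos was higher on the arrays numbered 2 by 1.93 in NSCL61 and 2.58 in NSCL61-sox11, and Fosb by 1.65 and 2.02; both are immediate early genes. The collagenase gene Mmp13 was higher by 2.16 and 2.00, Selenop by 2.11 and 1.94, Postn by 0.81 and 2.32, and Col6a3 by 1.05 and 1.69. In all 14 genes differed by at least 1 in the same direction in both lines, each higher on the arrays numbered 2. The median of the cholesterol synthesis list differed the same way, by 0.11 and 0.34, and that of the S phase list by -0.07 and -0.19.

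The chromosome shifts were weighed against technical explanations. An effect of signal level was argued against by 0 of 10000 level-matched random lists having a median as far from 0 as those of chromosomes 7, 10, 12 and 14. A few strongly changed neighbours were argued against on chromosomes 12 and 14. There 88.9% and all 8 of the blocks of about 50 genes lay below the 5th percentile of random blocks. On chromosome 7 as a whole 11 of 21 did and 1 lay above the 95th. Its blocks 14 to 21, from Pgm2l1 to Mrgprf, all lay below the 5th percentile, with medians of -0.335 to -0.125. This argues against a few changed neighbours for that stretch, which was picked after the blocks were seen. Variation between arrays was argued against by a largest difference of 0.0324 between arrays of a line on these 4 chromosomes. A difference in copy number between the lines, or between parts of their cells, may account for the pattern and cannot be told apart from others here. The brightest 153 genes of chromosome 12 and 139 of chromosome 14 had medians of -0.252 and -0.341, as it needs. These chromosomes had been picked for their low medians, so this was nearly fixed in advance and adds no support. The dimmest 153 and 140 had -0.05 and -0.07, short of the -0.1 set before this test but after the chromosomes were chosen. That part of the prediction was therefore not met. Signal near the floor can shrink a change, which was not tested for these genes, so the dimmest genes leave the question open. No DNA was measured.

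The higher fibroblast and meningeal markers may reflect fibroblast-like cells in the NSCL61-sox11 cultures, and this hypothesis was tested with 3 fibroblast transcripts below the level filter. Lum, Thy1 and Fap had a mean log2 fold change of -0.127 in the fit of all probe sets (upper 95% limit 0.098, under the 0.5 set beforehand), and none rose, which had been set down as evidence against it. That rule was wrong: picking markers below the filter left out the 8 that rose, and all 3 stay dim (3.80 to 4.88 in NSCL61-sox11), although Fap, Lum and Thy1 could have risen by 2.38, 2.31 and 0.292 without passing the filter. Of the abundant members, Col3a1 was at 9.65 and 10.69 (limma adjusted p = 0.12) and Dcn at 6.87 and 7.24 (adjusted p = 0.41). Such cells cannot be told apart here from a change of expression within the NSCL61-sox11 cells, and 6 of the 14 tested markers are also in other lists.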
